A study of Mus musculus with 4 samples.

How the data were processed

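Single cells of the small-intestinal epithelial layer were assayed in 4 samples, 2 of mice on a high-fat diet with l-NAME and 2 of mice on that diet with IPA, each a pool of 2 mice. Per the labels' protocols, the epithelial layer was released with EDTA and DTT, DAPI-negative cells were sorted, and libraries were made with 3′ v2 droplet chemistry with UMIs. The deposited values are whole-number UMI counts per gene and barcode, not normalized, per the file headers and the values. Cell Ranger 6.1.1 and the mm10 build are named in the submitters' processing notes, without a role or order. The filters on barcodes, the annotation and how the libraries were merged are not given in the sources used here. Genes carry symbols and no identifiers, and 550 of 555 genes of the fixed lists and 186 of 187 marker genes were found by symbol.

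The 4 libraries were told apart by the number on each barcode. No label or header used here ties a number to a sample, and no library was assigned to a diet from its values, order or size. The tests planned before the data were examined (edgeR on summed counts per cell class, on cell numbers and on gene lists, and an interaction of diet with cell class) were therefore not run. In their place, as fixed in advance for this case, each library's values are given without groups, means over libraries or p-values. Samples were grouped by their labels only to describe the design.

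Barcodes with at least 500 UMIs and 250 genes and at most 25% mitochondrial UMIs were kept, limits fixed before the data were examined. Of 44277 barcodes 25788 passed. Doublet scores were computed per library with Scrublet as in scanpy 1.11.5. Its automatic threshold marked 137, 5, 187 and 10 cells in libraries 1 to 4, under 0.5% in 2 of the 4. Whether the threshold failed there or few doublets could be detected was not tested. The 6% of cells with the highest score were removed in each library, 1546 in all, a rule chosen after seeing that result. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and 24242 cells were clustered with 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1.0, without batch correction. This gave 33 clusters, and the immune clusters were clustered again into 15 subclusters.

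Clusters were named from 25 marker sets fixed before the data were examined. The score limits for naming were set after seeing the data. The enterocyte set was not scored. A cluster that no other set named was called enterocyte-like if enough enterocyte markers were detected in it and its depth or leading genes met a further limit. Names end in -like because no annotation from the authors was used. T-like cells join 6 subclusters, 2 of them named by the CD4 T marker set and 4 in which neither the CD8 nor the gamma-delta set reached the limit for a name. Goblet-like cells join clusters 18 and 31, and cluster 31 also scored high for the cycling set. Cells left unnamed were cluster 21 (54, 344, 43 and 55 cells in libraries 1 to 4, or 0.93%, 5.14%, 0.725% and 0.946% of clustered cells), cluster 26 (0, 52, 154 and 1 cells, or 0%, 0.777%, 2.60% and 0.017%) and an immune subcluster of mixed T and enterocyte transcripts (6, 3, 75 and 2 cells, or 0.103%, 0.045%, 1.27% and 0.034%). Of its 86 cells, 60 held Cd3e and all held Fabp1, which nearly all T-like droplets also held. Fabp1 was at 5406 CPM in this subcluster against 1706 CPM in T-like cells, and Cd3e at 592 against 1406 CPM. The high fibroblast score of the subcluster came from few cells, 6 of which held Dcn. Paneth-like cells had a median of 100700 UMIs, of which 49.8% were alpha-defensin transcripts. They numbered 113, and 116 with doublets kept.

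For each class, UMIs were summed per library and divided by the class total to give CPM, with exact Poisson intervals. Shares have exact Clopper-Pearson intervals. A count of 0 is given with the limit of 3 counts. CPM and list medians per library are given for classes with at least 20 cells in that library. Cell numbers or shares are given for every class. Shares are also given where fewer than 20 cells were found for Paneth-like and tuft-like cells and for macrophage- and monocyte-like cells of library 3. Of 38 gene lists fixed before the data were examined, those with at least 3 members at a mean of at least 10 CPM were measured. Each member's log2 of CPM plus a prior of 1 CPM was set against the log2 of the median CPM of the 4 libraries plus the same prior, and the list's value is the median over members. It was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. T-like cells were compared between libraries 1 and 3 directly in the same way. A ranking of lists describes these libraries and is not a test of the diet.

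The list step was tested on simulated counts for enterocyte-like cells of the 4 libraries with 6470 genes in the step. Within 0.5 log2 units, 47 of 50 genes planted at -2, 48 of 50 at -1, 45 of 50 at 1 and 44 of 50 at 2 were recovered. A list planted at 1.5 was found at 1.32, one at -2 at -1.67 and one at -0.25 at -0.12. The reference median includes the shifted library and a prior is added to both sides, which makes a planted shift smaller by construction. How much each contributes, and whether anything else does, was not tested. Of 100 list medians with no planted shift, 1 lay beyond 99.5% of the random lists. The simulated genes varied independently around 1 pooled profile. This count therefore cannot show how the ranking behaves where list members vary together. A first version used a prior of 10 CPM, which shrank the planted values. The prior was set to 1 CPM after the real values with 10 CPM had been seen, and 10 CPM was kept as an alternative.

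The rule for named genes, fixed in advance for cells that no label assigns, takes the cell type markers and the list members with the highest mean CPM. It adds Ahr, Nr1i2, Cyp1a1, Cyp1b1, Ahrr, Tiparp, Cyp3a11, Abcb1a, Nnmt, Nampt and Sirt3 whatever their values. Hmgcs1 and Igkc in enterocyte-like cells were added after their values were seen. Predicted genes and variable segments of antigen receptors were not named. Positions come from the GENCODE annotation of GRCm38. Alternatives were other limits on mitochondrial UMIs (15% and 50%) and on UMIs and genes (1000 and 500), doublets kept, clustering at resolution 0.5 and 2.0, equal numbers of cells per library, and 6 added after seeing the data. A floor of 3 cells corresponds to 0.0522%, 0.0476%, 0.053% and 0.0521% of the named cells of libraries 1 to 4. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, with fixed seeds.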

Results

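The study profiled single cells of the small-intestinal epithelial layer of male C57BL/6J mice fed a high-fat diet with l-NAME, an inhibitor of nitric oxide synthases, with or without added indolepropionic acid (IPA), a tryptophan metabolite made by gut bacteria. The labels name 2 control samples and 2 samples whose diet held 562.5 mg IPA per kg. Feeding began at 8 weeks of age and lasted 7 weeks, and each sample pooled 2 mice. Viable cells of jejunum and ileum, from which the Peyer's patches had been removed, were sorted and counted by a droplet assay that reads the 3′ ends of transcripts and marks each captured molecule with a unique molecular identifier (UMI).

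The question behind the design was what dietary IPA changes in intestinal homeostasis. The deposited counts of the 4 libraries stood in 1 matrix, in which a number from 1 to 4 on each cell barcode separated the libraries. The labels and files used here did not say which number was which labelled sample. No library was therefore assigned to a diet, no comparison of IPA with control was made, and no p-value was computed. The values below belong to library 1, 2, 3 and 4, named by barcode number, which is not a replicate number. A difference between these libraries is a difference between pools of 2 mice, in which diet, mouse and preparation are not separated. Intervals are 95% intervals that cover counting error only.

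The matrix held 44277 barcodes and 744946003 UMIs over 32285 genes. Library 1 held 11558 barcodes and 183971338 UMIs, library 2 held 11987 and 209357877, library 3 held 11775 and 178052389, and library 4 held 8957 and 173564399. The median share of mitochondrial UMIs per barcode was 20.7% in library 1, 13.6% in library 2, 20.3% in library 3 and 13.1% in library 4. The filter on cell quality removed 41.8% of all barcodes, and the clustered cells had median depths of 26919, 26733, 21651 and 25690 UMIs in libraries 1 to 4. After removal of likely doublets and of 789 cells that no marker set named, 23453 cells remained, with 5744, 6296, 5657 and 5756 in the 4 libraries.

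Enterocytes are the absorptive cells of the villus. The enterocyte-like class, a name given only where no other marker set named a cluster, made up most of the epithelium in every library. They were 88.2% (95% CI 87.3 to 89.0) of the epithelial cells in library 1, 83.0% (82.1 to 83.9) in library 2, 79.6% (78.3 to 80.8) in library 3 and 90.8% (90.0 to 91.5) in library 4. Immune cells made up 8.29% (7.59 to 9.03) of the named cells of library 1, 0.222% (0.122 to 0.373) of library 2, 24.9% (23.8 to 26.1) of library 3 and 0.347% (0.212 to 0.536) of library 4. These shares corresponded to 476, 14, 1410 and 20 immune cells. Viability was the only stated sort criterion, and the median T-like cell held 3764 UMIs against 27383 in enterocyte-like cells, so shares of shallow cells can move with the UMI limit.

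**Figure D1:**
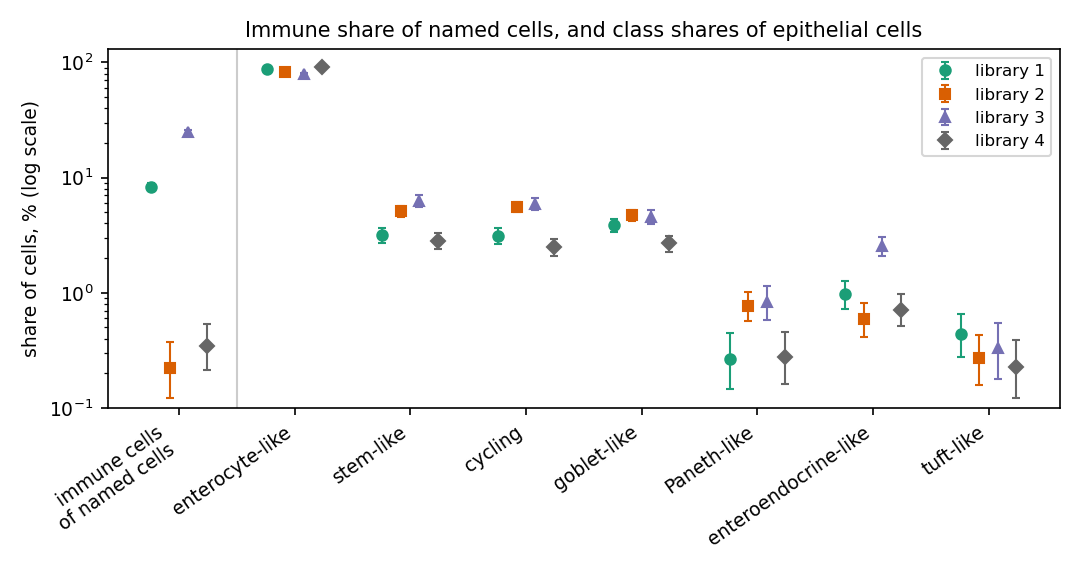
Share of immune cells among named cells (left of the line) and share of each epithelial class among epithelial cells (right), in percent on a log axis; each point is 1 library and bars are exact 95% binomial intervals. The immune share ran from 0.222% in library 2 to 24.9% in library 3, while the enterocyte-like share lay between 79.6% and 90.8% in all 4 libraries.

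Among the smaller epithelial classes, stem-like cells of the crypt were 3.17% of epithelial cells in library 1, 5.08% in library 2, 6.31% in library 3 and 2.82% in library 4. With a finer clustering the stem-like share was 3.26% in library 2 and 1.85% in library 4, and with cells of at least 1000 UMIs and 500 genes it was 3.31% in library 2. Cycling epithelial cells were 3.13%, 5.57%, 5.91% and 2.48% of the epithelium in libraries 1 to 4. With at least 1000 UMIs and 500 genes per cell, that share was 6.03%, 9.22% and 4.67% in libraries 1, 2 and 4. The enterocyte-like class includes cluster 13, with 124, 408, 144 and 211 cells in libraries 1 to 4, which had cell cycle genes among its leading genes. It also includes cluster 7, with 164, 434, 241 and 267 cells, and cluster 22, with 63, 273, 82 and 49. The enterocyte marker Apoa4 was at 1124, 439 and 370 CPM in clusters 7, 13 and 22. In the other clusters of the class it ran from 1043 to 55134 CPM. Goblet-like cells, which secrete mucus, were 3.85%, 4.71%, 4.52% and 2.69%.

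Paneth-like cells, the source of alpha-defensins at the crypt base, were few. There were 14, 48, 35 and 16 of them in libraries 1 to 4, or 0.266%, 0.764%, 0.824% and 0.279% of epithelial cells. A cluster of 0, 52, 154 and 1 cells with low UMI counts and defensin transcripts was left unnamed. Counting it as Paneth-like raised the share to 1.58% in library 2 and 4.29% in library 3. Enteroendocrine-like cells, the hormone-secreting class, were 0.968% (0.722 to 1.27) in library 1, 0.589% (0.415 to 0.811) in library 2, 2.54% (2.09 to 3.06) in library 3 and 0.715% (0.513 to 0.968) in library 4. With at most 15% mitochondrial UMIs per cell the enteroendocrine-like share was 1.71% in library 1 and 1.33% in library 2, where it was 1.17% with at most 50% and 1.26% with a coarser clustering. Tuft-like cells were between 0.227% and 0.437% of epithelial cells in the 4 libraries, from 13 to 23 cells each. In library 4 their share was 0.144% with at most 15% mitochondrial UMIs.

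T-like cells numbered 304 in library 1, 4 in library 2, 1110 in library 3 and 5 in library 4, and were the largest immune class in libraries 1 and 3. They were 63.9% (59.4 to 68.2) of the immune cells of library 1 and 78.7% (76.5 to 80.8) of those of library 3. B-like cells numbered 25, 2, 118 and 5, and antibody-secreting plasma-like cells 79, 7, 38 and 7. Plasma-like cells were 16.6% (13.4 to 20.2) of immune cells in library 1 and 2.70% (1.91 to 3.68) in library 3. NK and ILC1-like cells numbered 12, 0, 59 and 0, dendritic-like cells 27, 1, 57 and 1, and macrophage- and monocyte-like cells 25, 0, 8 and 2. The 8 of library 3 had a median of 834 UMIs, and their share of its immune cells fell from 0.567% to 0.212% with at least 1000 UMIs and 500 genes. Mast-like cells were found in library 3 alone, with 13 cells, and a finer clustering did not set them apart. Cycling immune-like cells numbered 4, 0, 7 and 0 in libraries 1 to 4. Class shares within libraries 2 and 4 rest on 14 and 20 immune cells and are not given. The dendritic-like share of immune cells was 5.67% in library 1 and 4.04% in library 3, and 2.11% and 2.54% with doublets kept. With a finer clustering it was 1.13% and 1.76%.

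The type I interferon list was highest in library 1 in enterocyte-like and goblet-like cells. In enterocyte-like cells the median log2 ratio of the 12 measured members of the type I interferon list to their median over the 4 libraries was 2.09 in library 1, -0.46 in library 2, 0.15 in library 3 and -0.24 in library 4. All 12 members lay above that median in library 1, and the list median exceeded those of all 10000 random lists matched on expression. Members were taken by their mean CPM over the 4 libraries, library 1 included. A member could thus be measured because of its value in library 1, which favours this library. Of the 116 list medians of this class over the 4 libraries, 34 lay beyond all random lists on 1 side, so this rank alone does not single out a list. Isg15, a ubiquitin-like protein induced by interferon, was at 284 CPM (counts per 10⁶ counts of the class) in library 1, 29.6 in library 2, 44.5 in library 3 and 18.4 in library 4. Irf7, a transcription factor of the interferon response, was at 171, 32.9, 59.8 and 47.1 CPM, and Ifit1, which binds viral RNA, at 138, 12.9, 34.8 and 20.0 CPM. Ifi27l2b, the most abundant member, was at 1802, 868, 1093 and 1054 CPM.

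Goblet-like cells of library 1 had an interferon list median of 1.40 over 13 measured members, with Isg15 at 157 CPM against 41.2, 30.9 and 18.6 CPM in libraries 2 to 4. In stem-like and cycling cells only 3 members were measured, and their medians in library 1 were 0.30 and 0.28. In enteroendocrine-like cells the medians of 10 members were 0.20, 0.23, -0.26 and -0.26 in libraries 1 to 4, and library 1 did not stand apart. Of the interferon-gamma list, 3 members reached the expression minimum in enterocyte-like cells, with medians of 0.78, 0.13, -0.10 and -0.75 in libraries 1 to 4. Among them Irf1 was at 72.4, 74.5, 63.4 and 48.6 CPM and Igtp, an interferon-induced GTPase, at 33.4, 10.2, 9.59 and 5.47 CPM. The enterocyte-like cells of library 1 lay mainly in clusters 5, 10, 14 and 3, which held 23.6%, 17.5%, 16.2% and 15.1% of them. Those of library 2 lay mainly in clusters 3, 1 and 17, with 19.9%, 15.97% and 13.0%. Those of library 3 lay mainly in clusters 2, 6 and 4, with 17.4%, 15.2% and 12.2%, and those of library 4 in clusters 2, 4 and 8, with 18.2%, 17.8% and 13.3%. All values for enterocyte-like cells compare these partly different clusters.

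Genes of antigen presentation differed by class of molecule. The MHC class II list, whose products present extracellular peptides, had a median of -2.95 in enterocyte-like cells of library 4, against -0.11, 0.89 and 0.10 in libraries 1 to 3. None of the 7 measured members of library 4 lay above the median of the 4 libraries. Cd74, the invariant chain of class II molecules, was at 267, 577, 357 and 15.97 CPM in libraries 1 to 4. H2-Ab1 was at 89.3, 162, 103 and 9.97 CPM, H2-Aa at 67.4, 145, 83.9 and 3.07 CPM, and Ctss, a lysosomal protease, at 91.1, 75.4, 70.3 and 66.9 CPM. The class II list median of library 4 was also low in stem-like cells (-3.19), cycling cells (-3.51) and goblet-like cells (-3.52). In enteroendocrine-like cells it was -0.50, 0.44, 0.10 and -0.61 in libraries 1 to 4, a much narrower range. Cd74 in stem-like cells was at 349, 524, 216 and 25.7 CPM. With a prior of 10 CPM in place of 1, the library 4 medians were -1.97, -2.07 and -1.31 in enterocyte-, stem- and goblet-like cells. The stem-like median was -2.57 with library 1 or 2 left out of the reference, and the goblet-like median was -2.91 without mitochondrial genes and -2.95 with doublets kept.

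The MHC class I list had medians of 0.44, -0.05, 0.02 and -0.14 in enterocyte-like cells of libraries 1 to 4, and all 13 measured members of library 1 lay above the median of the 4 libraries. B2m, the light chain of class I molecules, was at 1590, 921, 1158 and 999 CPM and H2-K1 at 1512, 828, 1217 and 1012 CPM. H2 genes, Reg3 genes, alpha-defensins and Cyp3a genes belong to families of similar sequence, and their counts are uncertain where counting could split reads among members.

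**Figure D2:**
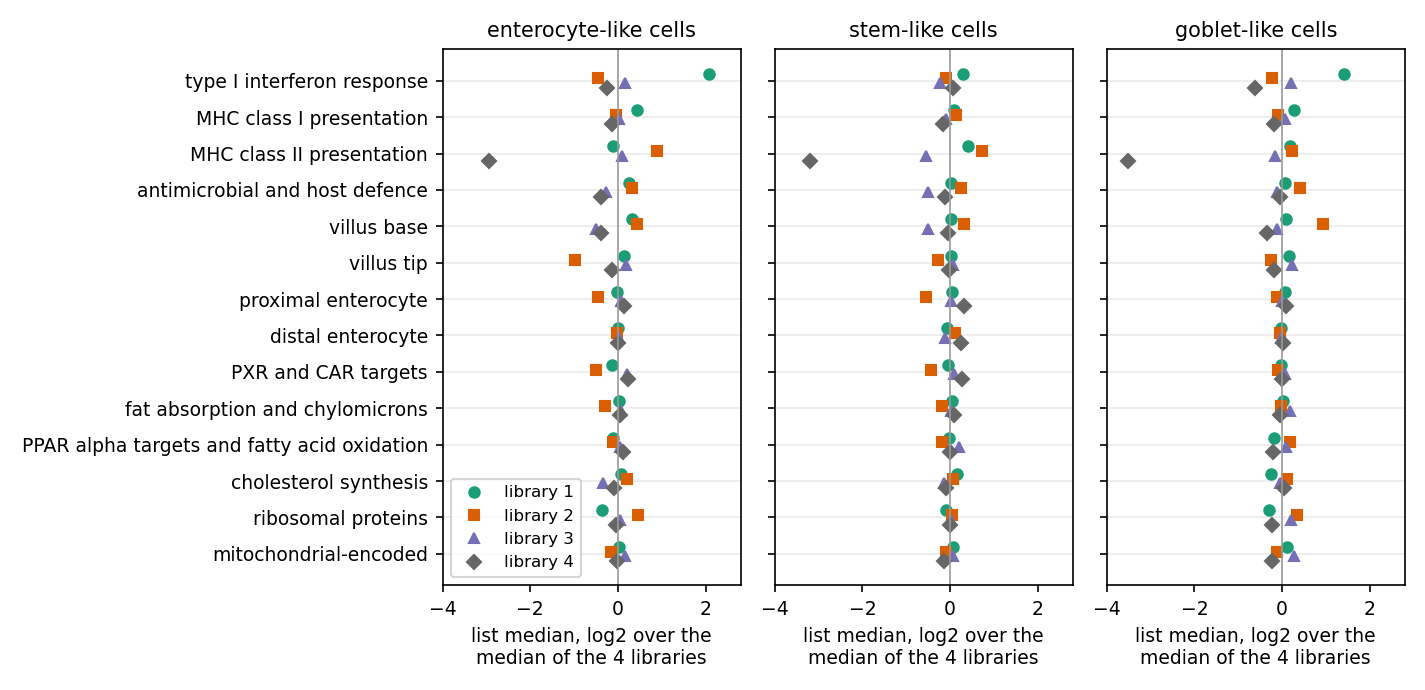
Median log2 ratio of the measured members of 14 gene lists to their median over the 4 libraries (x axis), in enterocyte-, stem- and goblet-like cells; each point is 1 library. The type I interferon list of library 1 lay at 2.09 in enterocyte-like cells, and the MHC class II list of library 4 lay at -2.95, -3.19 and -3.52 in the 3 classes.

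Among antimicrobial transcripts, Reg3b and Reg3g covered a wide range. Reg3b, a secreted lectin that acts on bacteria, was at 11770 CPM in enterocyte-like cells of library 1, 25354 in library 2, 1655 in library 3 and 1865 in library 4. Its relative Reg3g was at 3361, 7064, 602 and 624 CPM. Lypd8, which limits contact of bacteria with the epithelium, was at 2809, 3525, 1531 and 1554 CPM, and Pigr, the transporter of IgA, at 2299, 2174, 1704 and 1666 CPM. The list of antimicrobial and host defence genes had medians of 0.25, 0.33, -0.27 and -0.39, with 11 measured members. Reg3b, Reg3g and Lypd8 also belong to the list of villus base genes, which had medians of 0.33, 0.45, -0.51 and -0.39. The villus tip list had medians of 0.14, -0.99, 0.19 and -0.13, and its members Apoa4 and Ada, a purine enzyme, were at 6413 and 101 CPM in library 2. In the other libraries Apoa4 lay between 14102 and 15279 CPM and Ada between 401 and 616 CPM.

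Receptors that bind indoles and drugs, and their targets, were taken as a fixed group. Nr1i2, which encodes the pregnane X receptor (PXR), was at 56.2, 44.9, 59.4 and 50.6 CPM in enterocyte-like cells of libraries 1 to 4, and Ahr, which encodes the aryl hydrocarbon receptor (AhR), at 10.3, 8.67, 9.29 and 7.95 CPM. The list of PXR and CAR targets had medians of -0.14, -0.49, 0.20 and 0.24. In library 2 none of the 16 measured members lay above the median of the 4 libraries, whereas 14 did in library 3 and 14 in library 4. Cyp3a11, a cytochrome P450 of drug metabolism, was at 76.5, 24.999, 149 and 130 CPM, and Abcb1a, a drug efflux pump, at 133, 99.4, 187 and 163 CPM. The proximal enterocyte and villus tip lists were also low in library 2, at -0.46 and -0.99. Its Cyp3a11 value was 43.0 CPM with equal weights over bins of a distal minus proximal (region) score. Over bins of a villus tip minus villus base (zone) score it was 59.8 CPM. The region score left out Cyp3a11 but kept Gsta1 and Aldh1a1, which also belong to the PXR and CAR list. Its weights therefore do not separate region from that list. The 4 most abundant members were Gsta1 at 800, 753, 793 and 914 CPM, Sult1b1 at 639, 620, 621 and 616 CPM, Aldh1a1 at 396, 349, 630 and 613 CPM, and Cyp3a13 at 484, 328, 455 and 389 CPM.

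Cyp1a1, the cytochrome P450 most used as a readout of AhR activity, had 1132 UMIs in enterocyte-like cells of library 1 (9.59 CPM, 95% CI 9.04 to 10.2) and 943 in library 2 (6.65 CPM, 6.24 to 7.09). Library 3 had 0 UMIs, a count that allows up to 0.0322 CPM, and library 4 had 13 (0.10 CPM, 0.053 to 0.171). With doublets kept, the value of library 4 was 0.242 CPM. The further AhR targets Tiparp and Nqo1 varied less, Tiparp being at 33.7, 33.8, 27.3 and 38.4 CPM and Nqo1 at 35.2, 45.9, 42.4 and 49.6 CPM. Cyp1b1 and Ahrr had at most 1 UMI in the enterocyte-like cells of any library. The AhR list had too few members above the expression minimum for a list median. Nnmt, a methyltransferase of nicotinamide, had 0 UMIs in enterocyte-like cells of all 4 libraries, which allows up to 0.0322 CPM in the library with the fewest UMIs. Nampt, of NAD synthesis, was at 69.2, 50.1, 50.7 and 45.5 CPM, and Sirt3, a mitochondrial deacetylase, at 24.5, 23.5, 24.2 and 23.3 CPM.

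**Figure D3:**
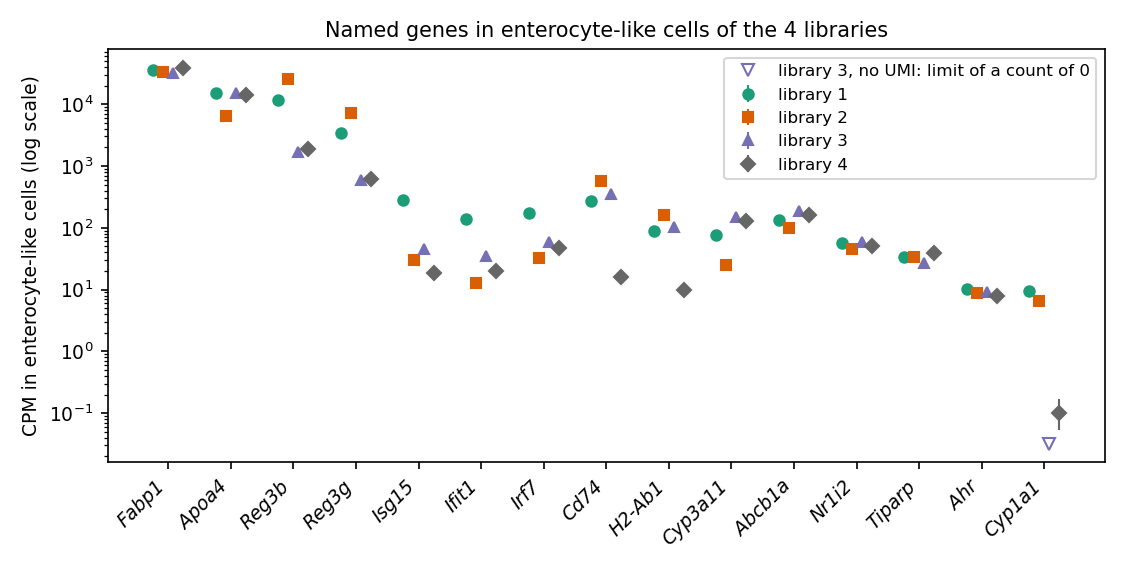
CPM of 15 genes in enterocyte-like cells on a log axis; each filled point is 1 library with its exact 95% Poisson interval, most of which are smaller than the points, and the open triangle is the limit that a count of 0 allows. Cyp1a1 lay at 9.59 and 6.65 CPM in libraries 1 and 2, at 0.10 CPM in library 4 and below 0.0322 CPM in library 3, while Ahr lay between 7.95 and 10.3 CPM.

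By cell class, Ahr and Nr1i2 had different distributions within a library. In library 3 Ahr was at 9.29 CPM in enterocyte-like cells, 110 CPM (95% CI 100.1 to 120) in T-like cells, 182 (132 to 244) in NK and ILC1-like cells and 220 (184 to 261) in dendritic-like cells. In library 1 it was at 10.3 CPM in enterocyte-like, 68.1 (53.9 to 84.9) in T-like and 145 (104 to 197) in dendritic-like cells. Nr1i2 was at 59.4 CPM in enterocyte-like cells, 23.7 in stem-like cells and 4.85 (3.04 to 7.34) in T-like cells of library 3. Abcb1a was at 187 CPM in enterocyte-like cells and 112 CPM in T-like cells of library 3. CPM is relative to the UMIs of a class. Median depths in library 3 were 3821 UMIs in T-like and 30497 in enterocyte-like cells, so these values do not compare molecules per cell.

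**Figure D4:**
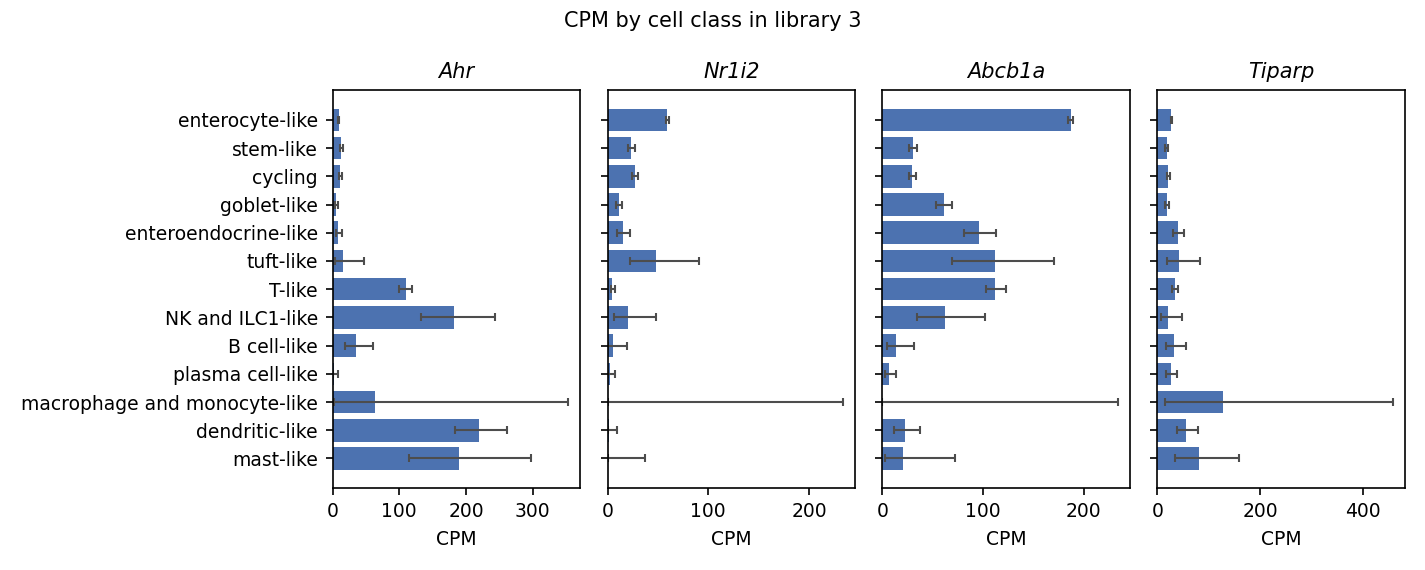
CPM of Ahr, Nr1i2, Abcb1a and Tiparp by cell class in library 3, the library with the most immune cells; bars are UMIs summed over the cells of a class, in CPM, with exact 95% Poisson intervals. Ahr was at 9.29 CPM in enterocyte-like cells and at 110, 182 and 220 CPM in T-like, NK and ILC1-like and dendritic-like cells. The bars of tuft-like, macrophage- and monocyte-like and mast-like cells rest on only 14, 8 and 13 cells. CPM is relative to the UMIs of a class and does not give molecules per cell.

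Genes of nutrient handling included abundant transcripts of enterocyte-like cells. Fabp1, the most abundant fatty acid binding protein, was at 36226, 33064, 32086 and 38372 CPM, and Fabp2 at 25933, 26731, 29939 and 33510 CPM. The list of fat absorption and chylomicrons had medians of 0.02, -0.29, 0.06 and 0.04, and only 1 of its 19 measured members lay above the median of the 4 libraries in library 2. The PPAR alpha and fatty acid oxidation list had medians of -0.12, -0.11, 0.05 and 0.11, with Acaa2, a thiolase, at 422, 488, 570 and 570 CPM. Cholesterol synthesis genes had medians of 0.08, 0.20, -0.35 and -0.09, and Hmgcs1 was at 74.2, 76.6, 49.2 and 59.2 CPM. Ribosomal protein genes had medians of -0.37, 0.46, 0.04 and -0.04. The proximal enterocyte list had medians of -0.02, -0.46, 0.07 and 0.14, and the distal list lay between -0.02 and 0.03.

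Of the 29 lists with at least 3 measured members in enterocyte-like cells, 4 had library medians more than 1 log2 unit apart, 9 between 0.5 and 1, and 16 at most 0.5. The 4 were MHC class II, type I interferon, interferon-gamma and villus tip. The NAD metabolism list had medians of 0.04, -0.09, 0.02 and -0.03, the tight junction list 0.02, -0.01, 0.09 and -0.12, and the nuclear-encoded respiratory chain 0.02, 0.05, -0.07 and 0.00. The median deviation of all 6494 genes measured in this class lay between -0.01 and 0.03 in the 4 libraries.

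T-like cells could be described in libraries 1 and 3, the only ones with at least 20 of them. They carried cytotoxic and intraepithelial features in both. Gzma, a granzyme, was at 24709 CPM in library 1 and 19152 in library 3, Gzmb at 3155 and 2436, and the chemokine Ccl5 at 24558 and 21234. Cd8a was at 1306 and 1261 CPM, Trdc, of the gamma-delta T cell receptor, at 741 and 756, Itgae, an integrin of epithelial residency, at 691 and 627, and Rgs1 at 1948 and 2690. The cytotoxic effector list had a median log2 ratio of library 1 to library 3 of 0.12 with 8 of 10 members higher in library 1, and the natural intraepithelial lymphocyte list one of -0.03 with 6 of 12. The list of immediate early and dissociation stress genes, which respond to cell handling, lay further apart at -0.33, with 4 of 18 members higher in library 1. It was 1 of 6 lists that lay below all random lists, the others being PXR and CAR targets (-0.84), mucus (-0.86), fat absorption (-0.55), proximal enterocyte (-0.62) and villus tip (-0.65). The type I interferon list had a ratio of 0.40 with 8 of 9 members higher in library 1, and Isg15 was at 79.3 and 50.7 CPM. The antimicrobial list, an enterocyte programme, lay at 0.30 in the same droplets, and the part that free RNA adds to the interferon ratio was not measured. Ahr was at 68.1 CPM in library 1 and 110 in library 3, Tiparp at 53.5 (41.0 to 68.5) and 33.5 (28.4 to 39.3), and Ahrr at 13.8 (7.89 to 22.4) and 6.39 (4.28 to 9.18). The T-like class joins subclusters whose pooled Gzma ran from 49.5 to 39022 CPM and whose Ahr ran from 61.2 to 178 CPM, in different proportions in the 2 libraries. These values therefore mix subcluster proportions with expression, and they compare 2 libraries and not the diets.

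Enterocyte transcripts were present in T-like droplets. Fabp1 was found in 299 of 304 T-like cells of library 1 and 1105 of 1110 of library 3, at 1263 and 1820 CPM, against 36226 and 32086 CPM in enterocyte-like cells, with median depths of 3575 and 3821 UMIs in T-like cells. The fat absorption list lay at -0.55 in T-like cells of library 1 relative to library 3. Igkc, an immunoglobulin light chain, was at 96.4 CPM in enterocyte-like cells of library 1, 4.76 in library 2, 97.3 in library 3 and 4.55 in library 4. Values of enterocyte genes in other classes at such levels were read as background.

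Of the named genes, the following lie on GRCm38 as protein-coding genes. Reg3b spans chromosome 6 from 78370657 to 78373466 on the plus strand, Cyp3a11 chromosome 5 from 145854426 to 145879964 on the minus strand, and Cyp1a1 chromosome 9 from 57687928 to 57703824 on the plus strand. Isg15 lies on chromosome 4 from 156199424 to 156200818 (minus), Cd74 on chromosome 18 from 60803848 to 60812652 (plus), Ahr on chromosome 12 from 35497974 to 35535038 (minus) and Nr1i2 on chromosome 16 from 38248323 to 38294824 (minus). The counts are sums over a gene, so no exon or untranslated region is singled out.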

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

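Of the alternatives below, 6 were chosen after seeing the data: CPM without mitochondrial genes, a prior of 10 CPM, a reference without each library in turn, members of at least 50 CPM, and other treatment of 2 unnamed groups of cells. In libraries 1 and 3 the immune share was 10.2% and 30.1% with at most 15% mitochondrial UMIs and 7.07% and 19.5% with at most 50%. It was 10.0% in library 1 with at least 1000 UMIs and 500 genes, and 23.8% in library 3 as a share of all clustered cells, which adds unnamed cells to the denominator. The type I interferon median of enterocyte-like cells was 2.02 in library 1 at resolution 2.0. With a prior of 10 CPM it was 1.66, -0.28, 0.10 and -0.16 in libraries 1 to 4, a shrinkage that the larger prior brings by construction. With members of a mean of at least 50 CPM, again with library 1 included, it was 1.97, 0.21 and -0.31 in libraries 1, 3 and 4. With at most 50% mitochondrial UMIs it was 0.19 in library 3 and -0.29 in library 4. With the reference taken without each library in turn it ranged from 1.86 to 2.45 in library 1, from -0.63 to -0.30 in library 2, from 0.00 to 0.32 in library 3 and from -0.40 to 0.00 in library 4. Except for that shrinkage, the denominator and the changed reference, the cause was not tested.

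Of 424 other cell shares under an alternative, 319 stayed within the counting interval, and apart from the changed denominator 21 shares above 0 differed by more than 1.5 times. Of 1400 CPM values of named genes, 667 stayed within the interval, and the 1 that moved by more than 1.5 times was Cyp1a1 in library 4. Of 1744 other list medians, 945 stayed within the interval and 46 changed sign, all with a size of at most 0.15 before. The 13 that moved by more than 0.5 log2 units were of the MHC class II list. Without the mitochondrial limit, median UMIs per cell fell to 12571 in library 1 and 8592 in library 3. No paired analysis was possible because no cell is assigned to a labelled sample. For the same reason the other settings of the test fixed in advance were not run: other size factors, library size only, low-count filters, DESeq2, voom, an estimated correlation, fry, composition scaling over classes, leaving out each labelled replicate, and the interaction. The immune classes of libraries 2 and 4 rest on 14 and 20 cells.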

Other observations

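The tests within bins of the region and zone scores, those with equal weights over bins for the interferon list, the T-like droplet test, the UMI limit test and the test of immune class ranks were chosen after the result was seen; the others were planned. Other immune classes held their own programmes in the libraries with at least 20 cells of them. Plasma-like cells carried Igkc at 499542 CPM in library 1 and 500615 in library 3, and Igha, the heavy chain of IgA, at 160847 and 148251 CPM. Dendritic-like cells carried Cd74 at 26078 and 21238 CPM and H2-Aa at 9016 and 7328 CPM, and B-like cells Cd74 at 14432 and 15555 CPM. Enteroendocrine-like cells carried the incretin gene Gip at 67140, 16259, 60149 and 41843 CPM in libraries 1 to 4 and Sct at 34645, 12266, 24221 and 24516 CPM. These rest on 51, 37, 108 and 41 cells. Goblet-like cells carried Zg16 at 216668, 168661, 162499 and 215715 CPM and Muc2, the main gel-forming mucin, at 15201, 12221, 15402 and 15623 CPM. Their cell cycle list lay at 0.22, 0.48, -0.33 and -0.75, in a class that includes a cluster with cycling markers of 21, 42, 18 and 8 cells out of 203, 296, 192 and 154, and their alpha-defensin list at -0.67, -0.03, -0.11 and 0.73. Stem-like cells carried Olfm4 at 2852, 2567, 3185 and 2049 CPM and Lgr5 at 48.1, 23.8, 49.3 and 25.7 CPM, and their stem cell list lay at 0.09, -0.15, 0.25 and -0.26.

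The values of the 4 unassigned libraries fell apart differently for different measures. The immune share was 8.29% and 24.9% in libraries 1 and 3 and 0.222% and 0.347% in libraries 2 and 4. Cyp1a1 in enterocyte-like cells was at 9.59 and 6.65 CPM in libraries 1 and 2, and at 0 and 0.10 CPM in libraries 3 and 4, and Reg3b was at 11770, 25354, 1655 and 1865 CPM in libraries 1 to 4. In the same class the MHC class II list was low in library 4 alone, at -2.95, and the type I interferon list high in library 1 alone, at 2.09. No T-like droplet of library 1 held a Cyp1a1 UMI, which allows up to 2.59 CPM there. These values say nothing of which library had which diet.

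The first pattern weighed was the high interferon list of library 1 in enterocyte-like cells, where shallow or damaged cells are argued against by 2.02 among cells of at least 20000 UMIs and at most 15% mitochondrial UMIs. A mix of villus regions or zones is argued against by the lowest median over 10 bins each of the region and zone scores, 1.17. Medians of 1.997 and 2.09 after equal weights over those bins also argue against it. The planned test did not decide. The goblet-like median of 1.40 lay above the bound of 1 set in advance, and the stem-like median of 0.30, over 3 members, lay under it. Goblet-like cells were not scored for region or zone, so their median cannot speak against such a mix. The cycling and enteroendocrine-like medians were 0.28 and 0.20, and the lowest bin was 0.89 with a prior of 10 CPM. For free RNA from a few cells, the planned test met the bound it set for that cause. Of the library's cells, thinned to 5000 UMIs, 19.3% lay above the 99th percentile of the other libraries, under the 20% set in advance. That share depends on the size of the shift and on the highest cells of the other libraries. It therefore cannot tell free RNA from RNA made in the cell. Median interferon-list UMIs of the thinned cells were 17 in library 1 and 5, 7 and 6 in libraries 2 to 4. The later test argued against free RNA. T-like droplets of library 1 held a mean of 2.60 interferon-list UMIs, while its median enterocyte-like cell held 68 against 33 in the next library. No biological explanation was tested, and an infection or another state of these mice, the diet and the preparation stay open, so an interferon response of this epithelium is at most a hypothesis.

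The second pattern was the share of T-like cells. The cell filter is argued against by unfiltered barcodes with at least 2 UMIs of Cd3d, Cd3e and Cd3g, which were 2.99%, 0.0334%, 12.0% and 0.067% of the 4 libraries, a highest to lowest ratio of 359. A higher UMI limit in some libraries is argued against by the 5th percentile of UMIs per deposited barcode, at most 1764 in any library, against a median of 3764 in T-like cells. How much of the immune fraction the sort, layer or loading took along cannot be told apart from a difference between mice or diets. Of the 3 other immune classes compared (B-like, plasma-like and macrophage-like), 1 ranked the libraries as the T-like share did. All 3 had higher shares of named cells in libraries 1 and 3 than in libraries 2 and 4. Plasma-like shares were 1.375%, 0.111%, 0.672% and 0.122% in libraries 1 to 4, and macrophage-like shares 0.435%, 0%, 0.141% and 0.035%. All of these counts in libraries 2 and 4 were under 10 cells. The mice and diets stay open and untested.

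The third pattern was the range of Reg3b and Cyp3a11 in enterocyte-like cells. With equal weights over bins of the region score, the highest to lowest ratio over libraries was 12.5 for Reg3b and 3.04 for Cyp3a11. This argues against the regional mix alone, as scored here, as the whole cause. With equal weights over bins of the zone score the ratio was 9.15 for Reg3b and 2.25 for Cyp3a11. The interval of the latter, 2.08 to 2.47, comes from resampling cells and covers cell sampling only. Villus position may account for part of the Cyp3a11 range. The scores left out Cyp3a11 and the Reg genes but kept other members of their lists. The region score kept Gsta1 and Aldh1a1 of the PXR and CAR list. The zone score kept Lypd8, Nlrp6 and Il18 of the antimicrobial list. Whether this overlap narrowed the ratios was not tested. The 2 scores were weighted 1 at a time and never together, so region and position as the whole cause of the Cyp3a11 range are not excluded. In libraries 1 and 3, CPM of both genes was at least 12.3 times as high in enterocyte-like as in T-like cells. This argues against free RNA as the main source of the enterocyte-like values there. Fabp1, also named in the planned prediction, was 28.7 and 17.6 times as high, against 33.3 and 19.3 for Reg3b and 17.7 and 12.3 for Cyp3a11. Library 2, with the highest Reg3b and the lowest Cyp3a11, had 4 T-like cells and could not be tested. Free RNA is therefore not excluded for the range. Bacterial exposure, diet and mouse were not tested and stay open.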
